A study of Homo sapiens with 12 samples.

How the data were processed

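RNA was sequenced from LM2 cells in 4 groups of 3 libraries: scramble shRNA, EZH2 shRNA, scramble siRNA and ZRANB1 siRNA. The authors deposited 1 table of FPKM values, with 26006 gene rows and 12 columns named as the libraries. Per the submitters' processing notes, TopHat2 2.1.1, SAMtools, Cufflinks 2.2.1 and Cuffdiff 2.2.1 were used with the human genome build hg19; their options, the gene annotation, the strand setting and any scaling between libraries are not given in the sources used here. FPKM divides fragments by transcript length and library size, so a gene with many fragments lowers the values of others, and short RNAs can receive very high values. The annotation used here for names was of another build, so no coordinates are given; 10770 of the 11929 tested symbols (90.3%) matched it or an older symbol in it.

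The values of a group stood in ascending order of their digits as text in all rows with 3 different values, which were 15773, 15751, 15454 and 15850 rows in the scramble shRNA, EZH2 shRNA, scramble siRNA and ZRANB1 siRNA groups; 16.7% would stand so by chance. In numeric order they would have been in 94.9%, 93.6%, 95.0% and 95.0% of these rows. A column therefore held values of different libraries in different rows, and its number named no replicate. Group means, SDs and the tests of single genes do not depend on the order, nor does camera at a preset correlation. A correlation between genes estimated from residuals does depend on it, since it treats a column as a library, and that estimate is given only to show this. There was no depth or scaling per library and no pairing by replicate number. Among rows with 3 values above 0 in a group, 0 held equal values, so no pair of libraries within a group had identical values.

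Of rows with the same symbol (442 symbols), the row with the highest mean was kept, and the 27 rows whose symbols had been turned into dates stayed separate. Values were tested as log2(FPKM + 1) for the 11929 genes with a mean of at least 1 FPKM over the 12 values, so a fold change is on the scale of log2(FPKM + 1) and understates the change of low genes. The test was limma 3.58.1 in R 4.3.3, with 1 mean per group, all 4 groups in the fit (8 residual degrees of freedom), a variance prior with an intensity trend, and Benjamini-Hochberg adjustment over genes. A gene was called at an adjusted p below 0.05. Gene lists (28, including markers of other cell types) with at least 5 tested members were tested with camera, from limma, at a preset correlation of 0.01, with adjustment over 24 lists and both comparisons together; the difference of effects was adjusted over 24 lists, and camera was also run with the correlation estimated from residuals, as planned. The text order fixes these residuals' columns whatever the correlation between genes, so no estimate free of the order could be had. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

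The gene lists, the groups, the tests, the rule for named genes and the alternatives listed first here were set before the data were examined. The rule took EZH2 and ZRANB1; for each comparison the 8 largest rises and 8 largest falls among called genes whose 3 values all lay outside the control range, leaving out small RNA and LOC symbols; up to 4 members of each described list by adjusted p (both of a list of 2); the 6 genes per direction changed the same way in both with the largest smaller change; and the 4 per direction called in opposite directions with the largest difference. Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, the 6 values of the compared groups alone, no variance trend, small RNA symbols left out, and an absolute log2 fold change of at least 1. After the text order was seen, 1 scaling factor per group, summing rows of a symbol, leaving out 1 value per gene after a random order, and estimating the correlation of camera for the difference of effects were added. Estimating that correlation after a random order was added too and is not reported, since a random order per gene removes any correlation between genes.

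The steps were tested on simulated FPKM values sorted as text. They were drawn from the real group means with 1 SD per gene, pooled over the 4 groups on the log2 scale. The draws had no correlation between genes. For the EZH2 comparison, with 11929 genes, 61.2% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 97.0% of those changed 4-fold were called; for the ZRANB1 comparison these shares were 53.7%, 77.6% and 93.9%. Of all calls, 3.53% and 5.06% were of unchanged genes. Precision is limited by 3 values per group, and the depth behind each value is unknown.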

Results

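RNA sequencing was used to profile LM2 cells, a derivative of the human breast cancer line MDA-MB-231 selected for spread to the lung. The 12 libraries fell into 4 groups of 3: cells with a scramble short hairpin RNA (shRNA), cells with an shRNA against EZH2, cells with a scramble small interfering RNA (siRNA), and cells with an siRNA against ZRANB1. EZH2 is the methyltransferase of Polycomb repressive complex 2 (PRC2) that places methyl groups on lysine 27 of histone H3. ZRANB1 is a deubiquitinase of the OTU family. The deposited table gave expression as FPKM, fragments scaled to transcript length and to the mapped fragments of a library, for 26006 rows, of which 11929 genes with a mean of at least 1 FPKM were tested. In each row with 3 different values in a group, these stood in the order of their digits as text, so a column did not follow 1 library from row to row. Group means and spreads were not affected by this order, whereas no value could be traced to its library. The sequencing depth was unknown, since the table held no counts. The labels did not say that the libraries of a group came from separate cultures, so p-values measured only the spread between these samples, which may be technical.

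The targeted genes were compared first. EZH2 fell with the EZH2 shRNA, from 35.4 ± 1.07 FPKM (SD, n = 3) with the scramble shRNA to 16.5 ± 0.680 FPKM, which was 46.6% of the control level. The log2 fold change was -1.06 with a standard error of 0.069 and an adjusted p of 1.34e-05. ZRANB1 stood at 11.4 ± 0.795 FPKM with the scramble siRNA and at 10.0 ± 1.31 FPKM in the libraries labelled ZRANB1 siRNA. That difference, a log2 fold change of -0.17 (95% interval -0.42 to 0.076), was not called by limma, with an adjusted p of 0.349. Without 1 value of a group, after a random order, the log2 fold change ran from -0.27 to -0.11. A lower level of the target transcript was thus not shown for the ZRANB1 siRNA group, and directions drawn from this group below are those of libraries labelled ZRANB1 siRNA. EZH2 was lower in the libraries labelled ZRANB1 siRNA as well, at 30.4 ± 2.08 FPKM against 48.6 ± 2.1 FPKM with the scramble siRNA, a log2 fold change of -0.66 and an adjusted p of 5.43e-05. A mixture of 44% EZH2 shRNA and 56% scramble siRNA by group means would have 34.5 FPKM of EZH2 and 12.6 FPKM of ZRANB1. ZRANB1 stood at 13.0 ± 1.17 FPKM with the scramble shRNA and 14.2 ± 1.94 FPKM with the EZH2 shRNA, with an adjusted p of 0.61. With 3 values against 3, a two-sided exact permutation test cannot go below p = 0.1, and it gave 0.1 for EZH2 in both comparisons, 0.2 for ZRANB1 with its siRNA and 0.5 for ZRANB1 with the EZH2 shRNA.

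**Figure D1:**
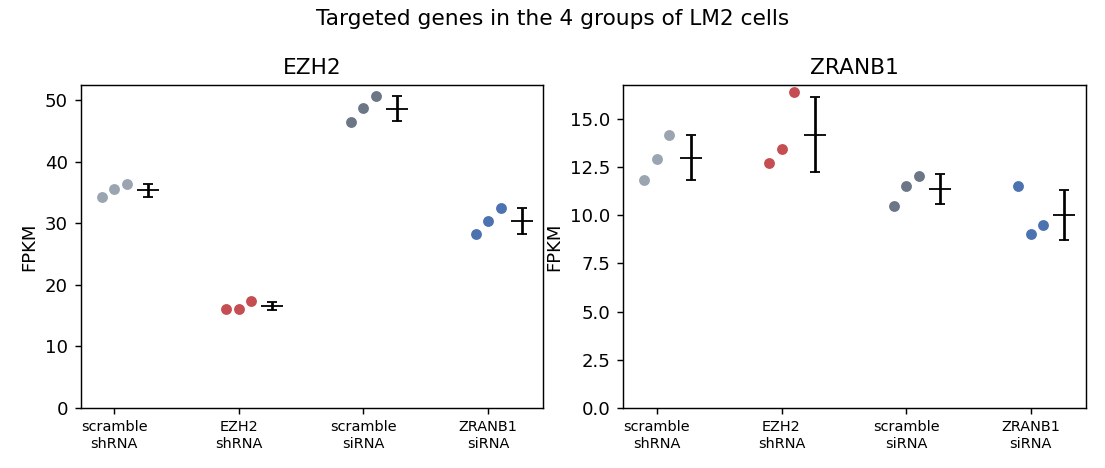
FPKM of EZH2 and ZRANB1 in the 4 groups of LM2 cells. Each point is 1 of the 3 values of a group, in the order of the deposited table, and the bar beside them is the mean with its SD; EZH2 averaged 16.5 FPKM with the EZH2 shRNA, while ZRANB1 averaged 10.0 FPKM in the ZRANB1 siRNA group against 11.4 FPKM in its control.

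The first comparison asked which transcripts change in LM2 cells when EZH2 is depleted. The collagenase gene MMP1 rose the most among named genes, from 27 ± 1.64 to 329 ± 16.0 FPKM (SD, n = 3), 12.2 times its control level. The stromelysin gene MMP3 rose from 2.42 ± 0.437 to 6.54 ± 0.526 FPKM, and the neutrophil chemokine gene CXCL8 rose from 134 ± 26.3 to 334 ± 48.9 FPKM. The metastasis-associated calcium-binding protein gene S100A4 fell from 406 ± 18.7 to 105 ± 16.9 FPKM, and the gelatinase gene MMP2 fell from 11.5 ± 1.23 to 3.62 ± 0.0829 FPKM. In all, 404 genes rose and 361 fell, which was 6.41% of those tested, and 36 of the 765 changed at least 2-fold.

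Other genes with large rises were PADI4, which encodes an enzyme that converts protein arginine to citrulline, with a log2 fold change of 1.61, GLUL, which encodes glutamine synthetase, with 1.42, the serine protease gene HTRA1 with 1.33, the cyclin gene CCND2 with 1.20 and the neuropeptide receptor gene VIPR1 with 1.10. HTRA1 went from 24.0 ± 1.63 to 61.6 ± 1.97 FPKM. Among the falls, the log2 fold change was -1.99 for FGF13, -1.80 for the drug-metabolizing cytochrome gene CYP3A5, -1.70 for the acute-phase gene SAA1, -1.45 for the protease inhibitor gene CST7 and -1.36 for the interferon-induced gene BST2. SAA1 went from 425 ± 21.9 to 131 ± 9.71 FPKM. The merged locus of SAA2 and SAA4 fell as well, by 1.34. SAA1 and SAA2 are near-identical copies, so the split of reads between them is uncertain.

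Interferon-stimulated genes were called lower as a list with the EZH2 shRNA. Of 33 tested members, 0 rose, 10 fell and 23 did not pass the test, and 14 fell when adjusted over the list alone. IFIT3 fell from 94.6 ± 3.33 to 58.5 ± 1.84 FPKM, IFIT1 from 30.9 ± 3.46 to 19.3 ± 2.39 FPKM and OAS2 from 8.31 ± 0.259 to 5.63 ± 0.428 FPKM. The list's median log2 fold change was -0.31, with an adjusted p of 5.66e-11 by camera. This call and those of the other lists below were lost with an estimated correlation (here adjusted p = 0.667), an estimate that the text order fixes and that therefore counts neither for nor against them. Genes of MHC class I antigen presentation had a median of -0.28, with 2 of 14 members lower (3 adjusted over the list alone) and an adjusted p of 2.47e-05 by camera. B2M, the light chain of class I molecules, fell from 1059 ± 103 to 791 ± 68.3 FPKM, and HLA-B from 278 ± 24.4 to 161 ± 32.1 FPKM; reads of HLA-B are shared with other class I genes.

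G1/S cell cycle genes and oxidative phosphorylation genes were called lower as lists, with few members passing the test of single genes. Of 48 G1/S cell cycle genes, 4 fell and none rose (5 fell adjusted over the list alone), among them the replicative helicase genes MCM4, from 74.0 ± 2.05 to 55.1 ± 0.443 FPKM, and MCM3, from 120.3 ± 3.88 to 94.8 ± 3.65 FPKM. The adjusted p by camera was 6.18e-06. Of 31 oxidative phosphorylation genes, 3 fell (13 adjusted over the list alone) around a median of -0.19, with an adjusted p of 4.87e-06 by camera. NDUFB9, a subunit of respiratory complex I, fell from 57.1 ± 6.50 to 29.6 ± 2.51 FPKM, and ATP5B, a subunit of ATP synthase, from 426 ± 15.1 to 349.9 ± 8.51 FPKM.

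Mesenchymal genes had 6 lower and 0 higher of 20 members (8 lower and 2 higher adjusted over the list alone) and an adjusted p of 0.0252 by camera. Besides S100A4 and MMP2, the cadherin gene CDH11 fell from 3.56 ± 0.226 to 1.77 ± 0.246 FPKM and the matrix protein gene SPARC from 116.4 ± 5.92 to 94.6 ± 6.14 FPKM. Of 24 cholesterol synthesis genes, 3 fell (5 adjusted over the list alone), with an adjusted p of 0.0436 by camera. INSIG1 fell from 48.5 ± 2.87 to 28.1 ± 3.40 FPKM, and the squalene epoxidase gene SQLE from 5.25 ± 0.903 to 3.09 ± 0.230 FPKM. OTU family deubiquitinases were the list called higher, with 2 of 13 members up (2 adjusted over the list alone) and an adjusted p of 0.00443 by camera. These were TNFAIP3, a feedback inhibitor of NF-kB signalling that is also in the NF-kB list, from 8.11 ± 0.268 to 18.0 ± 0.869 FPKM, and OTUB2, from 13.5 ± 0.402 to 22.3 ± 1.24 FPKM. The calls of the mesenchymal and cholesterol synthesis lists did not hold in each setting tried at the preset correlation, where their adjusted p ran from 0.00829 to 0.0956 and from 0.0154 to 0.147.

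Genes reported to be repressed by EZH2 in cancer cells were not called as a list. Only 18 of the 34 listed genes were tested, and 7 of 39 listed HOX cluster genes. Low or silent genes were left out by the filter, so neither list shows whether such genes rose. Of 18 tested members, 1 rose and 2 fell (3 and 2 adjusted over the list alone), with an adjusted p of 0.821 by camera; their median log2 fold change was -0.044 and their mean 0.037, of opposite sign. CCND2 rose from 1.04 ± 0.262 to 3.65 ± 0.257 FPKM, whereas the metalloproteinase inhibitor gene TIMP3 fell from 121 ± 4.96 to 78.1 ± 2.94 FPKM and the cell cycle inhibitor gene CDKN1C from 2.48 ± 0.415 to 1.5 ± 0.238 FPKM. Of 13 PRC2 subunit genes, 1 fell, EZH2 itself. HOX cluster genes had 1 higher of 7, HOXB9, at 2.98 ± 0.282 and 4.15 ± 0.405 FPKM. NF-kB and inflammatory genes had 4 higher and 0 lower of 21 (8 and 4 adjusted over the list alone) and an adjusted p of 0.0578 by camera; ICAM1, which encodes an adhesion molecule, rose from 39.1 ± 1.91 to 69.2 ± 2.97 FPKM. In all, 7 of 24 lists were called, 1 higher and 6 lower.

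The remaining lists were not called or had too few tested members for camera, and their members are given as higher and lower, with the numbers adjusted over the list alone in parentheses. These were 0 and 0 of 18 PRC1 subunits (0 and 0), 0 and 0 of 2 H3K27 demethylases (0 and 0), 0 and 0 of 4 MHC class II genes (0 and 1), 0 and 1 of 58 G2/M cell cycle genes (0 and 0), 1 and 1 of 5 CDK inhibitors (1 and 1) and 2 and 0 of 19 p53 target genes (2 and 1). They were also 0 and 0 of 12 BCL2 family genes (2 and 0), 1 and 1 of 11 epithelial genes (1 and 1), 3 and 3 of 17 genes of the lung metastasis signature (3 and 3), 0 and 0 of 8 Wnt target genes (0 and 1), 3 and 2 of 14 YAP target genes (3 and 2) and 0 and 0 of 20 unfolded protein and integrated stress response genes (0 and 0). Last came 1 and 1 of 23 hypoxia and glycolysis genes (2 and 1), 2 and 0 of 10 RNA interference genes (4 and 1), 0 and 2 of 7 luminal breast markers (0 and 3), 0 and 0 of 3 blood and endothelial markers (0 and 0) and 0 and 0 of 1 fibroblast markers (0 and 1). The cell cycle inhibitor gene CDKN1A rose from 52.4 ± 4.01 to 84.9 ± 8.77 FPKM, the desmosome gene DSP from 13.4 ± 0.599 to 21.5 ± 2.11 FPKM and the tissue factor gene F3 from 81.4 ± 3.71 to 126 ± 7.13 FPKM.

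The counts came from limma on log2 values with all 4 groups in 1 fit. With the 6 values of the EZH2 shRNA group and its control alone, 185 genes were called, 104 higher and 81 lower, and with 1 value of a group left out after a random order the count ran from 408 to 591. The calls of IFIT1, OAS2, B2M, HLA-B, MCM3, SPARC, SQLE, ATP5B, CDKN1C and HOXB9 named above did not hold in at least 1 of the settings tried. Of lists not called, those of NF-kB and inflammatory genes, of luminal markers and of the unfolded protein and integrated stress response were called in at least 1 setting, with a lowest adjusted p of 0.0112, 0.0222 and 0.0345.

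The other comparison asked which transcripts change when ZRANB1 is targeted. In the libraries labelled ZRANB1 siRNA, inflammatory genes stood far above the scramble siRNA control. The interleukin gene IL6 was at 105 ± 9.70 FPKM against 2.15 ± 0.272 FPKM (SD, n = 3), the complement gene C3 at 69.7 ± 5.61 against 0.324 ± 0.166 FPKM, and CXCL8 at 136 ± 27.7 against 2.02 ± 0.236 FPKM. MMP1 rose from 4.18 ± 0.347 to 175 ± 13.5 FPKM. In all, 1210 genes were higher and 775 lower, 16.6% of those tested, and 223 changed at least 2-fold, of which 211 were higher. Without 1 value of a group, after a random order, 926 to 956 genes were higher and 459 to 514 lower. With small RNA symbols left out, 1979 genes were called, and 1850 of them (93.5%) lay between the scramble siRNA and EZH2 shRNA groups. Lying between both groups does not by itself give the cause. Since a lower ZRANB1 level was not shown either, these counts cannot be read as a measure of the response to loss of ZRANB1.

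The scramble siRNA control itself stood far from the scramble shRNA control, which bears on each gene group of this comparison. IL6 was at 202 ± 6.88 FPKM with the scramble shRNA, C3 at 189 ± 12.6 FPKM, CXCL8 at 134 ± 26.3 FPKM and MMP1 at 27 ± 1.64 FPKM. Of the 11929 genes, 6036 differed between both scramble controls, 3045 higher and 2991 lower with the siRNA.

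Other large rises in the libraries labelled ZRANB1 siRNA were those of C15orf48, with a log2 fold change of 5.73, the chemokine gene CXCL1 with 4.85, the metallothionein gene MT1F with 4.62 and the collagen gene COL7A1 with 4.42. MT1F and CXCL1 have close paralogs, so their levels are uncertain. Falls among the named genes were smaller. The log2 fold change was -1.73 for the merged locus of CUZD1 and FAM24B, -1.30 for SOCS2-AS1, -1.25 for the bile acid binding protein gene FABP6, -1.22 for the apolipoprotein gene APOC1, -1.20 for NUDT8, -1.16 for SEMA3B, -1.11 for the inhibin subunit gene INHBB and -1.10 for the nuclear pore gene NUP210. SEMA3B went from 18.3 ± 2.52 to 7.69 ± 1.52 FPKM. The strand setting of the counting was not given, so SOCS2-AS1 cannot be separated from SOCS2.

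**Figure D2:**
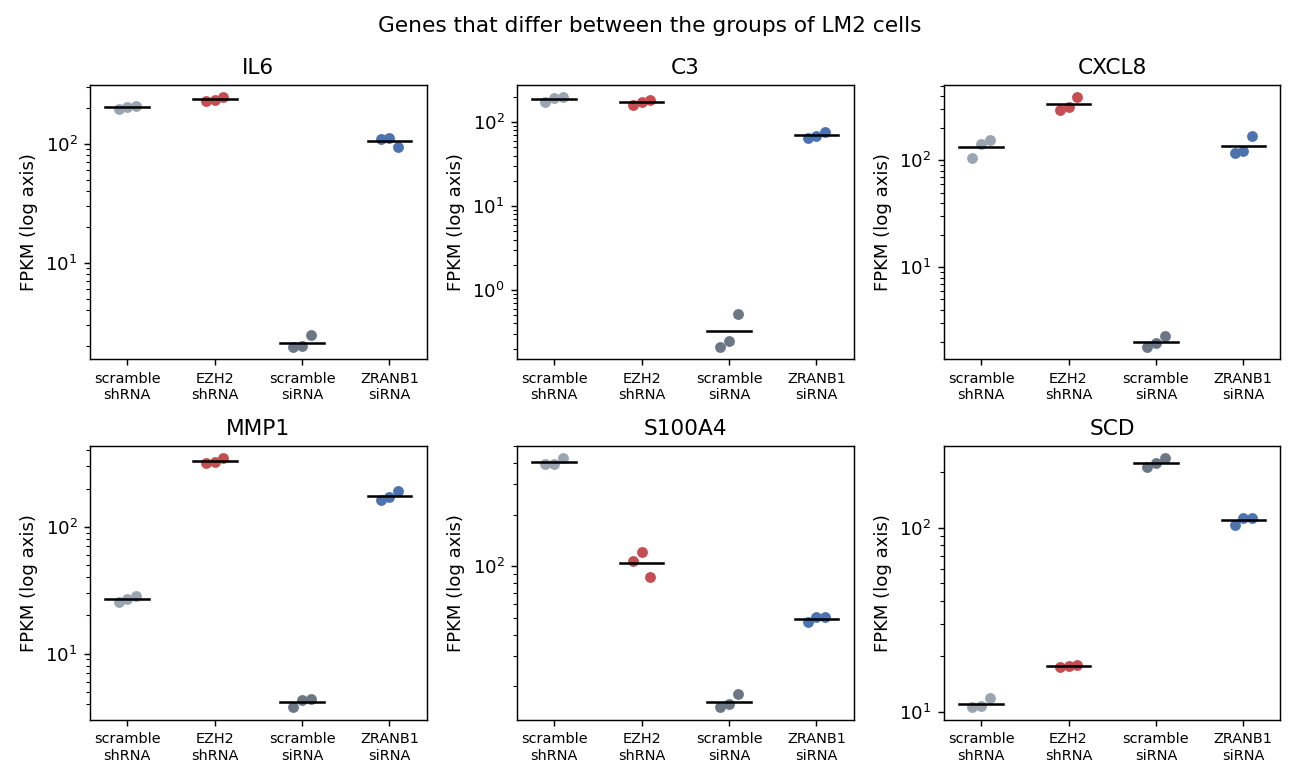
FPKM on a log axis of 6 genes in the 4 groups, with 3 values per group as points and the mean as a line. The scramble siRNA group stands lowest for IL6, C3, CXCL8, MMP1 and S100A4 and highest for SCD, and the ZRANB1 siRNA group lies between the scramble siRNA and EZH2 shRNA groups in all 6.

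NF-kB and inflammatory genes were called higher as a list. Of 21 members, 20 rose (21 adjusted over the list alone) around a median log2 fold change of 1.96, with an adjusted p of 5.57e-33 by camera. IL1B rose from 15.0 ± 0.912 to 340.2 ± 16.3 FPKM and the granulocyte growth factor gene CSF3 from 21.9 ± 1.07 to 360.4 ± 42.5 FPKM. All 21 members were lower with the scramble siRNA than with the scramble shRNA, with a median log2 difference of -2.29. The lung metastasis signature list had 14 higher and 2 lower of 17 members (15 and 2 adjusted over the list alone). Its adjusted p was 9.14e-15 by camera, and the direction of each member in the signature was not used. The matrix gene TNC rose from 2.72 ± 0.197 to 15.1 ± 0.185 FPKM and the cyclooxygenase gene PTGS2 from 3.16 ± 0.518 to 39.6 ± 5.58 FPKM, while ID1 fell from 153 ± 22.7 to 95.9 ± 10.9 FPKM. The scramble siRNA was lower than the scramble shRNA in 15 of these members.

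Hypoxia and glycolysis genes had 16 higher and 1 lower of 23 (17 and 1 adjusted over the list alone) and an adjusted p of 1.84e-12 by camera. The angiogenic factor gene VEGFA rose from 33.2 ± 2.89 to 131 ± 5.05 FPKM, the carbonic anhydrase gene CA9 from 0.600 ± 0.257 to 16.1 ± 1.22 FPKM and NDRG1 from 31.4 ± 0.548 to 98.9 ± 0.511 FPKM. The scramble siRNA was lower than the scramble shRNA in 20 of the 23. Mesenchymal genes had 13 of 20 higher (14 adjusted over the list alone) and an adjusted p of 1.22e-11 by camera. TGFBI rose from 24.8 ± 1.09 to 88.3 ± 6.51 FPKM, and 13 members were lower in the scramble siRNA than in the scramble shRNA. The fibroblast marker COL1A1 also rose, from 8.14 ± 0.539 to 17 ± 1.51 FPKM, with 24.6 ± 2.96 FPKM in the scramble shRNA group.

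Genes of MHC class I antigen presentation were all higher, 14 of 14 members (14 adjusted over the list alone), with an adjusted p of 2.26e-11 by camera. HLA-B rose from 24.4 ± 5.34 to 95 ± 19.8 FPKM and the peptide transporter gene TAP1 from 4.97 ± 0.677 to 12 ± 2.25 FPKM. Interferon-stimulated genes had 21 higher and 1 lower of 33 (22 and 1 adjusted over the list alone) and an adjusted p of 2.12e-08 by camera. The RNA sensor gene IFIH1 rose from 1.09 ± 0.113 to 4.27 ± 0.748 FPKM and CXCL10 from 0.0459 ± 0.0401 to 1.89 ± 0.284 FPKM. The scramble siRNA was lower than the scramble shRNA in 14 of 14 class I genes and 24 of 33 interferon-stimulated genes.

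Cholesterol synthesis genes were called lower as a list. Of 24 members, 19 fell (21 adjusted over the list alone) around a median log2 fold change of -0.55, with an adjusted p of 1.84e-12 by camera. FDFT1, which encodes squalene synthase, fell from 96.1 ± 1.27 to 58.2 ± 3.49 FPKM and FDPS from 172 ± 8.97 to 112 ± 5.50 FPKM, and 21 of the 24 were higher with the scramble siRNA than with the scramble shRNA. G2/M cell cycle genes had 12 of 58 lower, with an adjusted p of 5.93e-05 by camera, and G1/S cell cycle genes had 6 of 48 lower, with 3.67e-04; adjusted over the list alone the counts were 12 and 6. The phosphatase gene CDC25C fell from 16.3 ± 0.728 to 11.7 ± 0.269 FPKM, and the uracil glycosylase gene UNG from 93.0 ± 1.42 to 65.2 ± 2.57 FPKM; the scramble siRNA was higher than the scramble shRNA in 16 and 13 members of these lists and lower in 11 and 8. Oxidative phosphorylation genes had 5 lower and 1 higher of 31 (5 and 1 adjusted over the list alone) and an adjusted p of 0.00467 by camera; ATP5B fell from 678 ± 11.8 to 533 ± 9.02 FPKM, and 18 members were higher with the scramble siRNA than with the scramble shRNA. OTU family deubiquitinases had 5 of 13 higher (5 adjusted over the list alone) and an adjusted p of 0.00442 by camera. They were led by TNFAIP3, from 1.44 ± 0.0645 to 8.54 ± 0.438 FPKM, and OTUB2, from 2.76 ± 0.205 to 10.2 ± 0.469 FPKM. OTUD1 rose from 4.21 ± 0.112 to 10.3 ± 0.657 FPKM. In this list 6 members were lower with the scramble siRNA than with the scramble shRNA.

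Of 34 listed genes reported to be repressed by EZH2, 18 were tested. Among them 4 were higher and 4 lower (4 and 6 adjusted over the list alone). The adjusted p by camera was 0.772, with a median log2 fold change of -0.17 and a mean of 0.072, of opposite sign. SLIT2 rose from 1.08 ± 0.255 to 7.54 ± 0.652 FPKM and CDKN1C fell from 12.1 ± 1.76 to 7.12 ± 0.138 FPKM. Of 13 PRC2 subunit genes, EZH2 fell and JARID2 rose, from 8.83 ± 0.103 to 13.2 ± 0.584 FPKM. In all, 11 of 24 lists were called, 7 higher and 4 lower. These 18 calls of limma's camera over both comparisons rest on its preset correlation between genes. With an estimated correlation, which ran from 0.412 to 0.834, none of the 18 held, but the text order fixes the columns whatever the correlation between genes. The HOX cluster list was called without a filter on low values, with an adjusted p of 0.0339, the lowest over the settings tried, which went up to 0.241.

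In the libraries labelled ZRANB1 siRNA the lists that were not called or had too few tested members, given in the same way as higher and lower with the numbers adjusted over the list alone in parentheses, began with 0 and 0 of 18 PRC1 subunits (0 and 0), 1 and 0 of 2 H3K27 demethylases (2 and 0), 0 and 1 of 4 MHC class II genes (0 and 3), 0 and 2 of 7 HOX cluster genes (0 and 2), 1 and 2 of 5 CDK inhibitors (1 and 2) and 4 and 1 of 19 p53 target genes (4 and 3). They went on with 4 and 2 of 12 BCL2 family genes (4 and 2), 2 and 2 of 11 epithelial genes (2 and 3), 0 and 0 of 8 Wnt target genes (0 and 0), 3 and 3 of 14 YAP target genes (3 and 4) and 3 and 1 of 20 unfolded protein and integrated stress response genes (4 and 2). The others were 1 and 2 of 10 RNA interference genes (2 and 3), 1 and 0 of 7 luminal breast markers (2 and 1), 1 and 0 of 3 blood and endothelial markers (1 and 0) and 1 and 0 of 1 fibroblast markers (1 and 0). CDKN1A rose from 17.1 ± 1.76 to 49.2 ± 5.69 FPKM and the apoptosis regulator gene BCL2A1 from 0.544 ± 0.419 to 4.89 ± 0.829 FPKM.

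**Figure D3:**
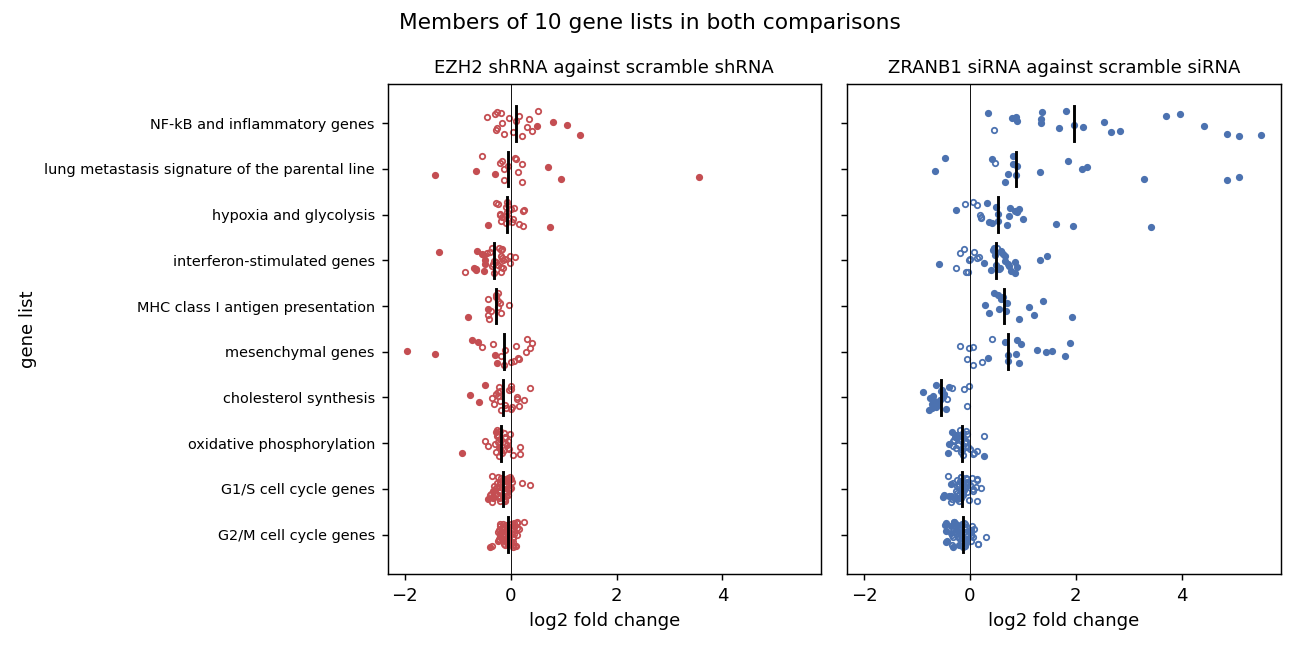
Log2 fold changes of the members of 10 gene lists with the EZH2 shRNA (left) and in the ZRANB1 siRNA group (right), each against its own scramble control. Each point is a gene, filled where its adjusted p was below 0.05, and the black line is the list's median, 0.11 and 1.96 for NF-kB and inflammatory genes.

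Both comparisons were then set side by side. MMP1, PADI4, CXCL8, MMP3, the elastase inhibitor gene PI3 and TNFAIP3 were higher in both, with TNFAIP3 up by 1.06 and 1.96 on the log2 scale. EZH2, the inflammasome gene NLRP2, ID1, LYPD6B, SQLE and the cyclin gene CCNA1 were lower in both, with NLRP2 at -0.78 and -0.75. S100A4, SAA1, the merged locus of SAA2 and SAA4 and C15orf48 were lower with the EZH2 shRNA and higher in the libraries labelled ZRANB1 siRNA, with S100A4 at -1.95 and 1.55. The merged locus of CUZD1 and FAM24B, SOCS2, SOCS2-AS1 and the fatty acid desaturase gene SCD went the other way, with SCD at 0.63 and -1.03. The calls of PI3, ID1, LYPD6B, SQLE, SOCS2 and SOCS2-AS1 with the EZH2 shRNA, and of LYPD6B in the libraries labelled ZRANB1 siRNA, did not hold in at least 1 of the settings tried.

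Of 335 genes called in both comparisons, 177 changed in the same direction and 158 in opposite directions. The number changed in the same direction was 63 with the 6 values of the compared groups alone, 115 with a filter at 5 FPKM and 105 to 149 without 1 value of a group. There were 127 genes higher in both, where independent lists would give 41.0, and 50 lower in both, where they would give 23.4. Genes lower with the EZH2 shRNA and higher in the libraries labelled ZRANB1 siRNA numbered 111 against 36.6, and the converse 47 against 26.2. Each of the 4 overlaps exceeded independence in a two-sided Fisher's exact test, with adjusted p of 8.84e-33, 4.4e-07, 5.62e-28 and 8.36e-05, so overlap was in excess whatever the direction. Both comparisons used separate controls but shared 1 estimate of each gene's spread. A gene of low spread was therefore more readily called in both, and the excess was not compared with a value that allows for this. Across the 11929 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.0222 and a Spearman correlation of 0.0940. The sign of the Pearson value was not stable: it was -0.0020 with a pseudocount of 0.1, 0.0869 without small RNA symbols and -0.0078 to 0.0547 without 1 value.

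The log2 fold change differed between the comparisons for 1251 genes, 824 with a higher log2 fold change in the libraries labelled ZRANB1 siRNA and 427 with a lower one. EZH2 fell by less there, by a difference of 0.39 (adjusted p = 0.0241). Among lists called in both comparisons, interferon-stimulated genes, MHC class I genes and mesenchymal genes went in opposite directions, and the difference of their effects had adjusted p of 1.73e-15, 6.93e-14 and 2.22e-12 by camera. All 3 were lost with an estimated correlation, at an adjusted p = 0.257, 0.189 and 0.257, which the text order fixes in the same way. The call of the mesenchymal list with the EZH2 shRNA did not hold in each setting tried. Each comparison had its own delivery method and its own control, so a difference between targets and a difference in delivery could not be separated.

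**Figure D4:**
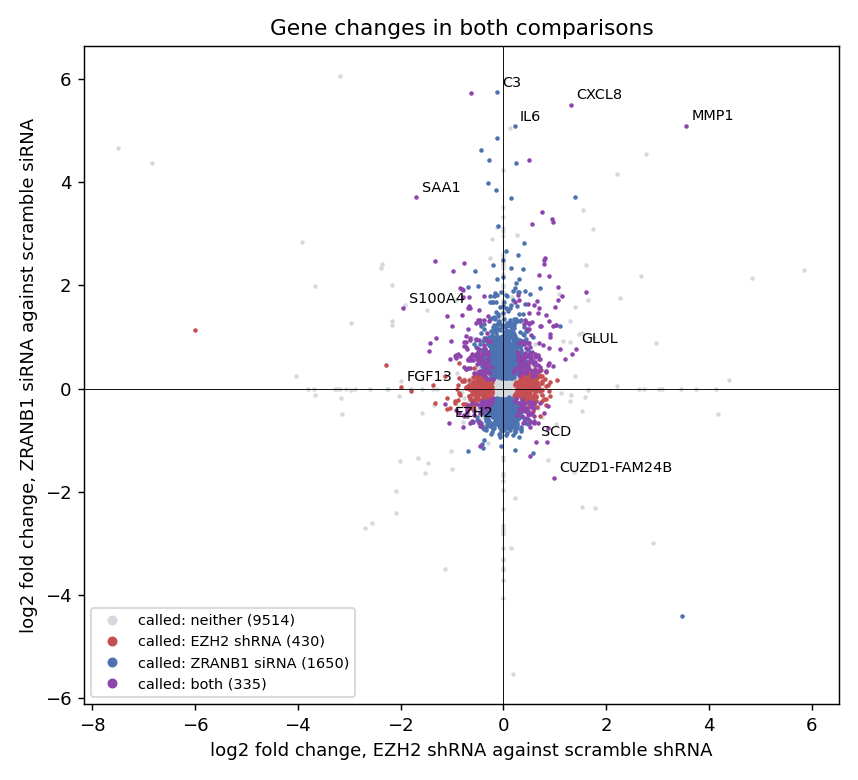
Log2 fold change of each of the 11929 tested genes with the EZH2 shRNA (horizontal axis) and in the ZRANB1 siRNA group (vertical axis), each against its own scramble control. Points are coloured by the comparison in which the gene was called; 335 genes were called in both, and MMP1 and CXCL8 stand high on both axes while S100A4 and SAA1 lie at the upper left.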

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

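The tests of mixing, graded response and target level in this part were chosen after the values had been seen, and so were the splits, while the test of the difference between comparisons was set before.

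The effects in both comparisons differed by the test of the difference for 1251 genes. For EZH2 itself the effect in the libraries labelled ZRANB1 siRNA minus that of the EZH2 shRNA was 0.39 on the log2 scale. Interferon-stimulated genes (median difference of effects 0.96), mesenchymal genes (1.08) and MHC class I genes (0.99) were called in opposite directions by camera at its preset correlation, although the call of mesenchymal genes with the EZH2 shRNA was lost with a filter at 5 FPKM and with the 6 values of the compared groups alone.

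The libraries labelled ZRANB1 siRNA lay between the scramble siRNA and EZH2 shRNA groups, which bears on each of these differences. Of the 175 genes with at least a 4-fold difference between those groups, 97.7% lay between them, at a median of 45.4% of the way to EZH2 shRNA on the linear FPKM scale (quartiles 40.7% and 50.7%), and a mixture of 44% EZH2 shRNA and 56% scramble siRNA left an RMS error of 0.143 on the log2 scale, against 0.373 with scramble siRNA alone and 0.154 with a 52% share on the log2 scale. The tables argue against a graded response of these 175 genes by 1 share of the log2 difference. Those higher and those lower in EZH2 shRNA differed by 36.1 percentage points in their median share on the log2 scale. On the linear scale the medians were closer but not equal, 44.7% for the 132 higher and 50.8% for the 43 lower genes. The shares of the lower genes were spread widely, with 5th and 95th percentiles of 30.1% and 75.1%, against 36.7% and 55.3% for the higher genes. A 42% mixture with scramble shRNA in place of EZH2 shRNA left a somewhat larger RMS error, 0.1675. For 181 genes at least 4-fold apart between both scramble groups, 96.1% of the ZRANB1 siRNA means lay between those groups. Their median was 43.2% of the way to scramble shRNA on the linear scale (quartiles 33.3% and 53.8%). An intermediate position was thus not particular to EZH2 shRNA. With small RNA symbols left out, 35 genes changed at least 2-fold by the EZH2 shRNA. Of these, 32 (91.4%) lay nearer to the mixture with EZH2 shRNA, which argues against scramble shRNA as the second kind for these genes only. RNA or cells of 2 kinds in these samples may explain most of the pattern as a hypothesis. So may a share of cells that took on an EZH2 shRNA-like state. However, a share of 56% scramble siRNA leaves each gene at least 56% of its scramble siRNA level. The named largest falls of the ZRANB1 comparison all stood lower, from 26.4% for the merged locus of CUZD1 and FAM24B to 42.5% for NUP210. The fitted mixture alone thus does not give the level of these genes, which were picked for the size of their fall. In addition, 25 genes were called above or below both groups, a count that leaves open whether a mixture alone would do for the other genes. Of these 25 genes, 17 lay nearer to the mixture with scramble shRNA. A simulated 40% mixture of 11740 genes used 1 pooled spread per gene and no correlation between genes. It gave 9 genes outside both groups and an RMS error of 0.119. Its genes with a 4-fold difference lay between both groups in 100%, with quartiles of 37.4% and 44.1%. An effect of ZRANB1 loss remains open as well, since ZRANB1 differed by -0.17 with an interval that includes 0, and it lay 0.31 below the mixture's 12.6 FPKM on the log2 scale, as EZH2 lay 0.18 below 34.5 FPKM, neither of which was tested.

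Splits of the values after a random order per gene are not splits of libraries. For the EZH2 comparison 10 splits are too few for a share under 0.05; the real count was 765 and the highest other 1, with 1 split, the real one, as large. For the ZRANB1 comparison 10 splits are again too few; the real count was 1985 and the highest other 2, with 1 split as large. For the difference between comparisons, 1 of 100 splits, the 10 of each comparison combined, gave as many genes as the real 1251. The highest other gave 611. Some of these splits keep the real grouping of 1 comparison, so their counts are not free of a real contrast. The splits do not settle the matter, also because the values carry no library identity.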

How the results depend on the processing

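No paired analysis was possible because the column numbers name no library, as the values of a group are in text order in each row. Scaling per library, quantile normalization and leaving out each library were not run for that reason, and the column number was fitted as a block only to show the effect of the order; the label splits planned as the null of the correlation across genes were not run either. Count-based tools were not run because the table held FPKM. Scaling per group, summing rows of a symbol, leaving out 1 value after a random order, and estimating the correlation of camera for the difference of effects were chosen after seeing the data; so was estimating it after a random order, which removes any correlation between genes and tests nothing. EZH2 with the EZH2 shRNA kept its direction and call in all settings, from -1.10 to -1.05 (adjusted p 4.35e-06 to 0.00502) and from -1.09 to -1.04 without 1 value. EZH2 in the libraries labelled ZRANB1 siRNA stayed called, from -0.68 to -0.65 (adjusted p 3.69e-05 to 0.0021) and from -0.71 to -0.61 without 1 value, and ZRANB1 stayed uncalled in both comparisons (adjusted p 0.32 to 0.44 with its own siRNA). Without 1 value, ZRANB1 ran from -0.27 to -0.11 with its own siRNA (adjusted p 0.172 to 0.646) and from 0.014 to 0.18 with the EZH2 shRNA (0.43 to 0.97). The cause of the changes below was not tested unless a smaller set of values or genes shows it.

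With a filter at 5 FPKM, 8952 genes were tested, and the EZH2 comparison gave 503 genes, 260 of them higher, and 115 genes changed the same way in both. With the 6 values of the compared groups alone, it gave 185 genes, 104 higher and 81 lower, and 63 changed the same way in both. At an absolute log2 fold change of at least 1 there were 36 (14 higher, 22 lower) in the EZH2 comparison and 223 (211 higher, 12 lower) in the ZRANB1 comparison. The correlation across genes was -0.0020 with a pseudocount of 0.1 and 0.0869 without small RNA symbols, and without 1 value it ran from -0.0078 to 0.0547. Without 1 value, the EZH2 comparison gave 408 to 591 genes (226 to 313 higher, 182 to 278 lower), the ZRANB1 comparison 459 to 514 lower genes, and genes changed the same way in both ran from 105 to 149. With an estimated correlation 0 of the 18 list calls held (3 of 48 tests by limma's camera had an unadjusted p below 0.05), and 0 of the 8 lists whose effects differed; the text order fixes the columns whatever the correlation between genes, so this estimate is no evidence about the lists. At the preset correlation, 16 to 20 lists were called without 1 value and 17 to 22 in the other settings; 2 calls were lost in at least 1 of these, mesenchymal genes (adjusted p up to 0.0956) and cholesterol synthesis (up to 0.147) with the EZH2 shRNA, and 4 were gained. Of 170 calls of named genes, 39 were lost in at least 1 setting, 42 were lost without 1 value, and 0 reversed.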

Other observations

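The tests in this part were chosen after the values had been seen.

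Both scramble controls of LM2 cells differed widely. The fatty acid desaturase gene SCD was at 11.1 ± 0.695 FPKM with the scramble shRNA and 225 ± 13.0 FPKM with the scramble siRNA (SD, n = 3), and SOCS2, a feedback inhibitor of cytokine signalling, at 2.28 ± 0.378 and 51.6 ± 3.82 FPKM. The keratin gene KRT19 was at 7.53 ± 1.62 and 47.4 ± 7.35 FPKM, and the inhibin gene INHBB at 0.271 ± 0.0922 and 6.43 ± 0.257 FPKM. In the opposite direction, CSF3 was at 948 ± 86.0 with the scramble shRNA and 21.9 ± 1.07 FPKM with the scramble siRNA, and the matrix gene TGFBI at 192 ± 4 and 24.8 ± 1.09 FPKM.

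A few genes in the libraries labelled ZRANB1 siRNA lay outside the scramble siRNA and EZH2 shRNA groups; they were chosen after their values were seen. The quinone reductase gene NQO1 was at 104 ± 8.33 FPKM against 66.4 ± 5.95 and 69.5 ± 5.25 FPKM, with 133 ± 8.19 FPKM in the scramble shRNA group. The ferritin light chain gene FTL was at 2354 ± 161 against 1512 ± 59.6 and 1708 ± 169.9 FPKM, with 2319 ± 175 FPKM in the scramble shRNA group, and the autophagy receptor gene SQSTM1 at 283 ± 17.2 against 213 ± 8.68 and 155 ± 16.6 FPKM, with 193 ± 13.1 FPKM there. The retinaldehyde reductase gene DHRS3 was at 0.740 ± 0.0483 against 1.86 ± 0.260 and 1.61 ± 0.377 FPKM, and ZMYND8 at 17.6 ± 1.16 against 22.2 ± 0.259 and 22.9 ± 1.66 FPKM, with 1.14 ± 0.155 and 24.6 ± 0.384 FPKM in the scramble shRNA group. In all, 18 genes were called above both groups and 7 below both. Of these 25 genes, 4 lay between both scramble groups.

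The gap between both scramble controls, with 6036 genes changed, was not 1 shift of scale, since 49.6% of them were lower and the others higher with the siRNA, whereas 1 factor moves all genes one way; the log2 differences over all genes had an SD of 0.699. Delivery, vector and culture of the controls cannot be told apart here, since each delivery method had 1 scramble group, and no biological explanation was tested.

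Columns with the same number deviated together, with correlations of their deviations from the group means of 0.0818 to 0.359 between EZH2 shRNA and its control and 0.186 to 0.372 between ZRANB1 siRNA and its control. A candidate explanation is the text order, which held in 100% of the rows with 3 different values in each group. Since 0 rows were out of text order, a number names no library. The pattern therefore says nothing about a shared day or batch of libraries, which could not be tested. A fit with the column number as a block called 4389 and 5473 genes in the text-ordered values, in place of 765 and 1985 without it.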
